A study of Arabidopsis with 8 samples.

How the data were processed

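RNA of 12-day-old Arabidopsis seedlings was measured at time 0 and after 30 min of dehydration in 2 genotypes, wild type (WT) and dcp5-1, which is named as an allele of DCP5. Per the labels, plants grew on solid medium at 22 °C with 16 h of light and 8 h of dark, and dehydration took place on filter paper in dim light at 60% humidity until the fresh weight was near 60% of its start. Per the labels' protocols, 100 ng of RNA per sample was labelled together with spike-in RNAs. Each of 8 two-colour Agilent arrays carried the time 0 RNA and the 30 min RNA of 1 genotype, with 4 arrays per genotype. Replicates 1 and 2 carried the 30 min RNA in Cy5, and dye-swaps 1 and 2 carried it in Cy3. The series' design text calls the 4 arrays of a genotype biological replicates, and each counted as 1 replicate. Nothing states whether a dye-swap repeats the RNA of the replicate with its number, so averaging these pairs first was one of the alternatives. After the dye effect was taken out, a replicate correlated with the dye-swap of its number at −0.29 to −0.040. With the other dye-swap it correlated at −0.40 to −0.17. These ranges overlap and do not settle the question. If the pairs shared RNA, each genotype would hold 2 independent samples, and the SEs, SDs and p-values below would overstate the precision.

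Per the file headers, Agilent Feature Extraction version 10.7.3.1 wrote the scanner files, while the submitters' processing notes name version 8.5.1.1. The deposited scanner files hold spot intensity in several columns: the median pixel brightness of the spot and of its background, with no normalization, and a processed intensity that Feature Extraction had background-subtracted and dye-normalized. The deposited LogRatio column holds log10 of Cy5 over Cy3 of the processed intensities, with the value 0 at spots not above background. A deposited p-value column gives the error-model p-value of each log10 ratio, and was not used. The deposited series table holds log2 ratios of 30 min over time 0, as found from its values. On each array 43553 probes with a single spot were compared with log2 of the processed Cy5 over Cy3 intensity, turned in sign on the dye-swaps, and 0 differed by more than 0.001. The scale and the direction of that table are therefore settled, and no column was centred further. Its column medians were −0.045, −0.030, −0.062 and −0.090 for WT replicates 1 and 2 and dye-swaps 1 and 2, and −0.0082, −0.0028, −0.12 and −0.0026 for the same arrays of dcp5-1.

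The choice of tests, gene lists, named genes and alternatives was made before the data were examined. It named mean spot signals, which the files do not contain, so median spot and background signals were used. Background was corrected with normexp (offset 50), each array was normalized by loess with control spots at weight 0, and ratios of dye-swapped arrays were turned so that positive values are higher at 30 min. Outlier spots were set aside (116 probe values), and repeated spots of a probe were averaged. The arrays hold 43603 probes other than controls. Of these, 38413 are named by 1 of 29030 loci, and 5190 carry another name and were left out of the tests of genes. For the 7320 loci with more than 1 probe, the probe with the highest mean intensity was used. A gene was tested when its probe was well above background on all 4 arrays of at least 1 genotype at 1 time, which left 21331 genes. The reference table held 21121 of their loci and a symbol for 9132, and other genes kept the locus of the array file. The share of probes well above background lay between 69.5% and 74.6% in the 16 channels. No spot was saturated, and the number of arrays limits the precision. Spike-in slopes lay between 0.896 and 0.914.

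Log ratios were fitted with limma 3.58.1 in R 4.3.3, with data.table version 1.17.8 for reading and python 3.11.15 for lists and plots. One fit of the 8 arrays held the response of each genotype and a dye term, with 5 residual and 9.37 prior degrees of freedom, and gave the difference between the responses as a contrast. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and counts are given also for changes of at least 2-fold. Genotypes were compared at time 0 and at 30 min by limma's separate-channel analysis after Aquantile normalization between arrays (intraspot correlation 0.563), over the 21289 genes with values on all 8 arrays. A gene well above background on none of the arrays of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against the dim group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background. Errors are standard errors (SE) from the fit, or standard deviations (SD) between arrays, on the log2 scale.

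Each step was tested on simulated data made from the real arrays with 50 genes changed at each of 4 sizes. For the difference in response, limma recovered 36, 50, 49 and 50 genes at log2 changes of 0.25, 0.5, 1 and 2, and for time 0 it recovered 39, 47, 49 and 50. The noise for time 0 was scaled down from a spread that also held differences between genotypes. The counts and false shares for time 0 therefore do not measure the power or the error of the real fit. Over 10 draws, a mean of 3.33% of the calls for the difference were false, and 11.1% of the calls at time 0 (16.4% in the highest draw), which is above the 5% that the threshold allows. With the channels of time 0 alone the mean was 5.24%, and among calls of at least 2-fold in the separate-channel fit it was 0.412%. Counts of at least 2-fold therefore lead the account of time 0 and 30 min. In simulated lists, the 1 shifted list was called and 0 of the other 24 were. The noise of their genes was simulated without correlation, so this does not test for false calls in lists of correlated genes.

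The size of the response was compared with genes chosen on arrays other than the one measured. The 200 genes with the largest rise and the 200 with the largest fall were taken from balanced pairs of arrays of 1 genotype, 1 of each dye orientation. The value of an array was the median log2 ratio of those genes, averaged over the pairs that did not hold that array. The 4 values per genotype were compared by an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. With no difference simulated, 1 of 50 draws passed the threshold for each of the 4 sets. No gene differed between genotypes in those draws. Where single genes differ, genes chosen as extreme in 1 genotype tend to be more extreme in it, and the draws do not test this.

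The 25 gene lists were ABA synthesis and catabolism, ABA receptors, ABA clade A PP2C phosphatases, ABA kinases and bZIP factors, dehydration and ABA effector genes, DREB, ERF and ZAT stress transcription factors, touch and early wound response, jasmonate synthesis and signalling, heat shock and oxidative stress, mRNA decapping and decay machinery, auxin early response, type-A cytokinin response regulators, expansins and xyloglucan endotransglucosylases, aquaporins, photosynthesis, root tissue markers, guard cell markers, circadian clock, sugar starvation and darkness, seed storage and seed maturation, salicylate and pathogen defence, reference genes, cytosolic ribosomal proteins, chloroplast-encoded transcripts and mitochondrion-encoded transcripts. Of the members written, 9 had a symbol found in no table and were left out. The ribosomal list holds the 7 loci whose description names such a protein. Lists with at least 5 genes measured were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stood camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. Members were counted with p adjusted over all genes, and the count adjusted over the list alone is given where it differs. Lists at 30 min were only counted.

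The genes named were the 10 with the largest rise and the 10 with the largest fall in each comparison, among genes with a primary symbol in the reference table, an adjusted p under 0.05 and the same direction on all 4 arrays of the genotype. For a difference between genotypes, all 4 arrays of one had to lie above all 4 of the other. Up to 4 members per list with the smallest adjusted p were named too, including those known to the table by a synonym, and always DCP5, CCL, SEN1 and EXLA1, which have served as reporters of mRNA decay. Alternatives covered background correction, normalization within and between arrays, the filter on dim genes, the probe rule, the prior, array weights, the dye term, averaged dye-swap pairs, the thresholds, the replicate label as a block, single channels, the deposited ratios, the set test, the number of genes chosen for the response size and leaving out each array. All 4 arrays of WT lay on 1 slide and all 4 of dcp5-1 on another, so slide and genotype cannot be told apart, and no fit with the slide as a block could be made.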

Results

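The series measured the transcript response of Arabidopsis seedlings to 30 min of dehydration in WT and in dcp5-1, with 4 two-colour arrays per genotype. No sample held seedlings that were handled alike but kept from losing water. Effects of handling, dim light or elapsed time therefore cannot be told apart from those of water loss. The dehydration response below stands for the whole change from time 0 to 30 min. DCP5 is a component of the mRNA decapping machinery that resides in processing bodies. On each array the time 0 RNA and the 30 min RNA of 1 genotype were hybridised together. The response was thus read within arrays, and the genotypes were compared between arrays. In each genotype the 30 min RNA was in Cy5 on 2 arrays and in Cy3 on 2 arrays. Of the 29030 loci with a probe, 21331 were tested. Across genes, which are not independent replicates, the log2 ratios of 2 arrays correlated at 0.988 to 0.994 within a genotype and dye orientation, at 0.960 to 0.972 between the orientations of a genotype, and at 0.908 to 0.937 between genotypes. After the fit the median SD between arrays was 0.062 on the log2 scale over all genes. For 18 probes with repeat spots it was 0.047, where the value of a probe on an array was the mean of its spots. Between the single repeat spots on 1 array it was 0.055. A mean of spots varies less than a single spot, so these values do not show how much of the spread between arrays is technical. The p-values measure only the spread between these samples, which can be technical. The 4 arrays of each genotype shared 1 slide that held no array of the other, and this applies to every comparison between genotypes.

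DCP5 (AT1G26110) was lower in dcp5-1 on every array at both times. With the probe used for the gene, the normalized level at time 0 was 11.09 ± 0.039 (log2, SD, n = 4) in WT and 8.77 ± 0.079 (SD, n = 4) in dcp5-1. This was a 5.0-fold lower level (log2 difference −2.32, exact two-sided permutation p 0.0286, the smallest p the design allows). At 30 min the level was 5.56-fold lower (log2 difference −2.48). The other 3 probes of the gene gave log2 differences of −5.05, −1.06 and −1.09 at time 0, so that the size of the loss depended on the probe. Every probe was well above background on all 4 dcp5-1 arrays at both times. The files do not say which part of the gene the allele affects, so the remaining signal does not show an intact transcript. DCP5 did not pass the test for a dehydration response in WT (log2 change 0.078, limma adjusted p 0.0588) or in dcp5-1 (−0.077, 0.0605). With the LogRatio column both responses passed in limma, with the WT value turned in sign (−0.086, adjusted p 0.0499, range 0.0196 to 0.581) and the dcp5-1 value at −0.17 (adjusted p 0.00229). That column put the median of all genes at −0.14 in WT and −0.12 in dcp5-1. With median centring the dcp5-1 response passed at −0.18 (limma adjusted p 0.000338, range 0.000338 to 0.329). The difference between the responses of DCP5 was −0.15 (limma adjusted p 0.0205), with p between 0.00567 and 0.193 over the alternatives. Leaving out 1 array moved these limma calls across the threshold. The WT response passed without WT replicate 1 (adjusted p 0.0196) or dcp5-1 replicate 2 (0.0484), and the dcp5-1 response passed without WT replicate 1 (0.0486), WT replicate 2 (0.0455), dcp5-1 replicate 2 (0.0330) or dcp5-1 dye-swap 2 (0.0472), all by limma. The difference missed the limma threshold without WT replicate 2 (adjusted p 0.0918), WT dye-swap 1 (0.0515), dcp5-1 replicate 1 (0.0793) or dcp5-1 dye-swap 1 (0.0566).

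**Figure D1:**
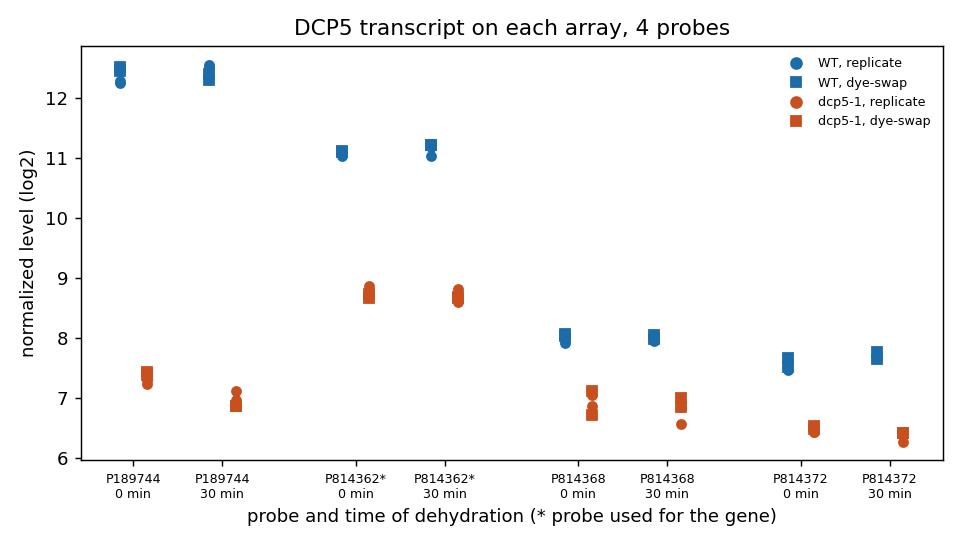
Normalized level (log2) of the 4 DCP5 probes at 0 and 30 min on each of the 8 arrays, with WT in blue and dcp5-1 in orange, circles for replicates and squares for dye-swaps. Each point is 1 array, the asterisk marks the probe used for the gene, and every dcp5-1 point lies below every WT point of the same probe and time.

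The first comparison asked which transcripts change during 30 min of dehydration in WT. The largest rises were those of WRKY40, a transcription factor (80.1-fold, log2 6.32 ± 0.039 SE, n = 4), BPS3 (69.5-fold), the calmodulin-like genes CML37 (58.9-fold) and CML38 (52.8-fold), and LOX3 (52.0-fold), a lipoxygenase of jasmonate synthesis. DDF1 (51.9-fold) and RRTF1 (51.2-fold), which encode AP2/ERF transcription factors, rose with MYB15 (47.6-fold), CYP94B3 (45.4-fold), which oxidises the active jasmonate, and LOX4 (42.6-fold). The largest falls among genes with a primary symbol included those of IAA29 (5.64-fold, log2 −2.50 ± 0.037 SE, n = 4), which encodes an Aux/IAA protein, SAUR19 (5.63-fold), SAUR22 (4.95-fold) and SAUR63 (4.57-fold). BRH1, a RING finger gene that responds to brassinosteroid, fell 5.23-fold, and RTFL16, OFP16, P1R1, GDU1 and HB52 fell between 4.52-fold and 5.07-fold. Each of these 20 genes moved the same way on 4 of 4 arrays, as the rule for naming genes required. The limma adjusted p was at most 3.57e-19 for the rises and 2.92e-17 for the falls. In all, 1509 genes rose and 279 fell at least 2-fold. Without the fold criterion, limma called 15317 of 21331 genes, 7646 higher and 7671 lower, most of them by small amounts (median absolute log2 change over all genes tested 0.16).

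Among the gene lists, the early stress regulators rose as whole groups in WT. All 22 genes of the DREB, ERF and ZAT list rose, by a median log2 of 3.76, with DDF1 at 5.70, ZAT12 at 4.90, ORA47 at 4.52 and AZF2 at 3.71 (camera adjusted p 1.37e-16, and 0.0404 with an estimated correlation). All 13 genes of the touch and early wound list rose, by a median of 4.69, among them ACS6, an ethylene synthesis gene (5.37), CAF1b, a deadenylase gene (4.84), and WRKY33 (4.75) (camera adjusted p 1.36e-11, and 0.0331 with an estimated correlation). All 24 genes of jasmonate synthesis and signalling rose, by a median of 3.40, with OPCL1 at 4.24 and JAZ7 at 4.49 (camera adjusted p 7.34e-16, and 0.0331 with an estimated correlation). Of 27 dehydration and ABA effector genes, 21 rose and 4 fell (5 adjusted over the list alone), with RD29A at 2.91, COR15A at 2.65, ERD10 at 2.26 and NAC055 at 2.09 (camera adjusted p 3.29e-05, and 0.0331 with an estimated correlation, over 26 of the genes). Of 22 auxin early response genes, 15 fell and 5 rose, with SAUR16 at −2.90 and SAUR14 at −2.35 (camera adjusted p 0.000712, and 0.0452 with an estimated correlation). Of 16 salicylate and pathogen defence genes, 14 rose and 1 fell, with CBP60G at 3.72 and PAD4 at 2.22 (camera adjusted p 4.77e-06, and adjusted p 0.0738 with an estimated correlation).

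The other lists called in WT moved less. Of 12 root tissue markers 10 fell and 0 rose, with EXPA7 at −0.55 and SHR at −0.48 (camera adjusted p 0.00485, and adjusted p 0.0738 with an estimated correlation). Of 66 chloroplast-encoded transcripts 42 fell and 3 rose, by a median of −0.12 (camera adjusted p 0.00204, and adjusted p 0.414 with an estimated correlation). Of 18 aquaporins 10 fell and 2 rose, with TIP2;3 at −0.65 (camera adjusted p 0.0455, and adjusted p 0.356 with an estimated correlation). Among the expansins and xyloglucan endotransglucosylases, which loosen and remodel cell walls, 13 of 19 fell, EXPA1 among them (−1.32), while XTH18 (4.66), XTH17 (3.36) and XTH19 (2.25) were among the 5 that rose (camera adjusted p 0.0455, and adjusted p 0.157 with an estimated correlation). That list's median was −0.42 and its mean 0.072, and fry gave it the upward direction (fry adjusted p 8.36e-05 in limma). The camera call for expansins was lost without WT replicate 1 (adjusted p 0.0534), with processed signals (0.0644) and with median centring (0.102), over a range of 0.0201 to 0.102. The camera call for aquaporins was lost without WT replicate 1 (adjusted p 0.0816) or replicate 2 (0.0522), with processed signals (0.0567) and with median centring (0.102), over the same range.

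The remaining lists had no camera call in WT. Members of the hormone lists moved both ways. Of 12 genes of ABA synthesis and catabolism 7 rose and 3 fell, with the catabolic genes CYP707A3 at 5.25 and CYP707A1 at 3.06 and the synthesis gene NCED3 at 2.52. Of 9 ABA receptor genes 1 rose and 6 fell. Of 7 PP2C genes 6 rose and 1 fell, with HAI1 at 1.08, and of 9 type-A regulators 2 rose and 6 fell, with ARR9 at −1.42. Heat shock genes rose in 6 of 8 and fell in 2, photosynthesis genes fell in 11 of 20 (9 adjusted over the list alone), and guard cell markers fell in 4 of 5 and rose in 1. Of 17 clock genes 6 rose and 9 fell, of 11 sugar starvation genes 1 rose and 7 fell, of 10 seed genes 2 rose and 5 fell, and of 6 reference genes 2 rose and 1 fell. The lists of ABA kinases and bZIP factors (4 rose and 4 fell of 8), of decapping and decay machinery (6 and 6 of 24), of ribosomal proteins (2 and 1 of 7) and of mitochondrion-encoded transcripts (27 and 3 of 58, or 22 and 3 adjusted over the list alone) had medians between −0.011 and 0.072 that changed sign under at least 1 other scaling.

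The second comparison put the same question to dcp5-1. The largest rises there were those of PP2-A5 (80.2-fold, log2 6.33 ± 0.033 SE, n = 4), CYP94B3 (78.5-fold), CYP94C1, a second oxidase of the active jasmonate (68.6-fold), LOX3 (67.8-fold), FRB1 (59.4-fold), SRO5 (57.6-fold), DDF1 (56.3-fold), LOX4 (52.3-fold), BPS3 (46.3-fold) and ERD7 (41.2-fold). The largest falls were those of P1R1 (7.08-fold), RTFL16 (6.85-fold), the thionin gene THI2.1 (6.68-fold, log2 −2.74 ± 0.045 SE, n = 4), OFP16 (6.57-fold), RTFL17 (6.49-fold) and BRH1 (6.36-fold), followed by IAA29, RTFL21, HB52 and BBX15 at 6.26-fold to 5.57-fold. Each of these 20 genes moved the same way on 4 of 4 arrays, again as the naming rule required. The limma adjusted p was at most 2.11e-19 for the rises and 2.66e-17 for the falls. In all, 1587 genes rose and 430 fell at least 2-fold, and limma called 16456 genes without the fold criterion, 8188 higher and 8268 lower. Of the genes that rose at least 2-fold, 1354 did so in both genotypes, where independent lists would share 112. Of those that fell at least 2-fold, 233 were shared, where independent lists would share 5.62, and 0 genes had calls of at least 2-fold in opposite directions. Across genes, which are not independent replicates, the responses of the genotypes correlated at r = 0.940 (Spearman's rho 0.849).

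The gene lists called in dcp5-1 were largely the regulators, effectors and auxin genes called in WT. All 24 jasmonate genes rose (median log2 3.5), among them JAZ10 at 4.98 (camera adjusted p 1.77e-14, and adjusted p 0.0504 with an estimated correlation). Of the DREB, ERF and ZAT genes 21 of 22 rose and 1 fell (median 2.57; camera adjusted p 1.18e-11, and adjusted p 0.0868 with an estimated correlation). All 13 touch and early wound genes rose (median 3.18; camera adjusted p 6.30e-10, and adjusted p 0.0504 with an estimated correlation). Of the effector genes 19 of 27 rose and 5 fell, with LTI30 at 2.65 and NAC019 at 2.41 (camera adjusted p 0.000282, and adjusted p 0.0504 with an estimated correlation). Of the salicylate and defence genes 13 of 16 rose and 3 fell, with SARD1 at 2.77 (camera adjusted p 0.000313, and adjusted p 0.121 with an estimated correlation). Auxin genes fell in 15 of 22 and rose in 5 (camera adjusted p 0.00563, and adjusted p 0.0887 with an estimated correlation). Of 11 sugar starvation genes 10 fell and 1 rose, with SEN1 at −1.57 and DRM1 at −1.0 among the falls and EXLA1 at 2.78 as the rise (camera adjusted p 0.00324, and adjusted p 0.103 with an estimated correlation). Expansins and related genes fell in 15 of 19 and rose in 4, with a median of −0.37, a mean of 0.015 and EXPA1 at −2.24 (camera adjusted p 0.0191, and adjusted p 0.110 with an estimated correlation). Median centring ended that camera call (adjusted p 0.0515, with 0.00535 to 0.0515 over the alternatives).

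Photosynthesis genes fell in 14 of 20 and rose in 4 in dcp5-1 (15 and 4 adjusted over the list alone), with LHCB4.2 at −0.52 (camera adjusted p 0.0242, and adjusted p 0.463 with an estimated correlation). The arrays split by dye: the list's median was 0.044 and 0.10 on the replicates and −0.49 and −0.44 on the dye-swaps (mean −0.20 ± 0.31 SD, n = 4). With no dye term LHCB2.2 (−0.41, adjusted p 0.0777) and LHCA1 (−0.33, adjusted p 0.144) missed the limma threshold. In WT the list split alike, at 0.25 and 0.23 on the replicates and −0.40 and −0.33 on the dye-swaps. Aquaporin genes fell in 12 of 18 and rose in 3, with TIP2;1 at −0.55 (camera adjusted p 0.0316, and adjusted p 0.463 with an estimated correlation). Mitochondrion-encoded transcripts rose in 34 of 58 and fell in 2 (33 and 2 adjusted over the list alone), by a median of 0.11, or 0.19 with processed signals (camera adjusted p 0.0210, and adjusted p 0.463 with an estimated correlation). The camera calls for aquaporins (adjusted p 0.0549, with 0.0124 to 0.0634 over the alternatives) and mitochondrion-encoded transcripts (0.0513, with 0.00837 to 0.0513) were lost without dcp5-1 dye-swap 2. The aquaporin call (0.0541 and 0.0634) and the photosynthesis call (camera adjusted p 0.0591 and 0.107, with 0.00809 to 0.107 over the alternatives) were also lost with processed signals and with median centring. None of the 11 lists called by camera in dcp5-1 was called with an estimated correlation, against 5 of 10 in WT, and this difference between genotypes was not itself tested.

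The third comparison asked whether the response differs between dcp5-1 and WT, by the contrast of the 2 responses. The largest negative differences, as log2 of the dcp5-1 response minus the WT response, were those of THI2.1 (−2.70), the Nudix hydrolase gene NUDT21 (−2.60) and CBF2 (−2.59 ± 0.053 SE, n = 4 per genotype). They were followed by ERF5 (−2.45), RHL41, also called ZAT12 (−2.32), the mitochondrial carrier gene DIC2 (−2.30), STZ, also called ZAT10 (−2.30), ERF104 (−2.23), ACS6 (−2.19) and NUDT4 (−2.08). In the other direction lay SAG13, a senescence-associated gene (2.77 ± 0.056 SE, n = 4 per genotype), DXPS1 (2.25), the lipid transfer protein gene LTP4 (2.09), the acetyltransferase gene NATA1 (2.04), CYP94C1 (1.84), the alpha-amylase gene AMY1 (1.82), the protease inhibitor gene KTI1 (1.77), ELI3-2 (1.77), the beta-glucosidase gene DIN2 (1.76) and GPT2, a glucose 6-phosphate transporter gene (1.58). A difference in response can also reflect a gap at time 0. The genes named both here and at time 0 below differed there with the opposite sign. In dcp5-1 at time 0, SAG13 (log2 −3.41), DXPS1 (−3.25), AMY1 (−2.64) and DIN2 (−2.38) were lower and THI2.1 (2.29) was higher. For all 20 genes the 4 arrays of one genotype lay above the 4 of the other, as the naming rule required. The limma adjusted p was at most 3.34e-11. In all, 130 genes had a response at least 2-fold smaller or more negative in dcp5-1 and 59 one at least 2-fold larger or less negative. Of the genes that rose at least 2-fold in either genotype, 104 were among the former and 31 among the latter. Without the fold criterion limma called 9526 of 21331 genes, 4037 higher and 5489 lower in dcp5-1, and 5412 with no dye term.

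**Figure D2:**
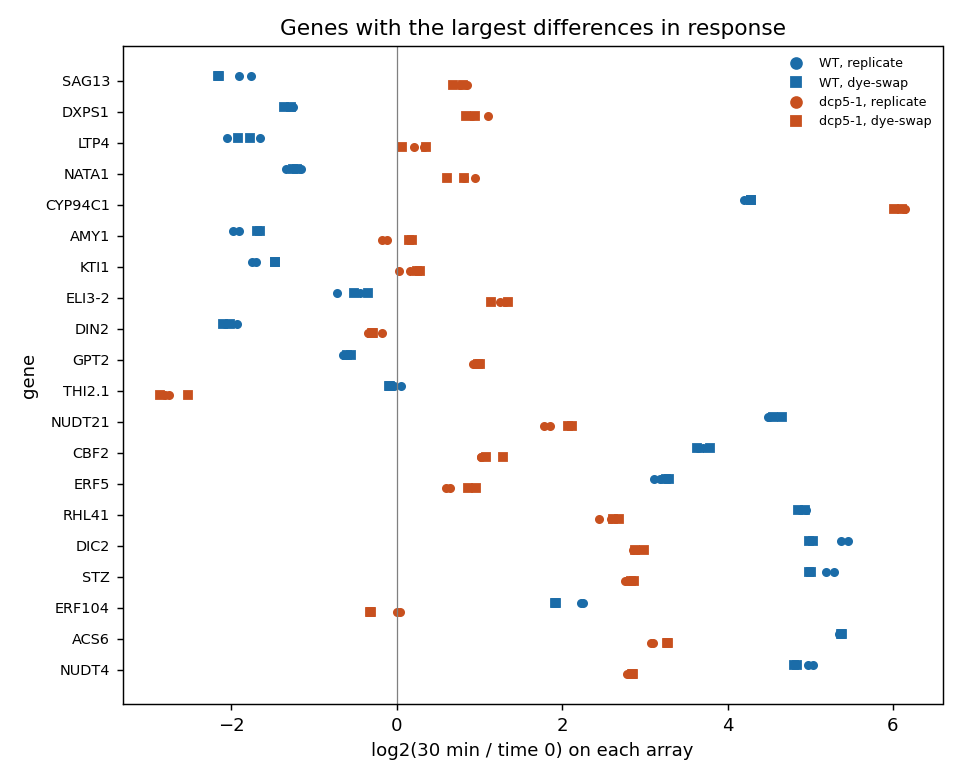
Log2 ratio of 30 min over time 0 on each of the 8 arrays for the 10 genes with the largest positive and the 10 with the largest negative difference in response, WT in blue and dcp5-1 in orange, circles for replicates and squares for dye-swaps. Each point is 1 array. The naming rule required the 4 arrays of one genotype to lie apart from the 4 of the other, as for SAG13 (difference 2.77) and THI2.1 (difference −2.70).

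Among the lists, 18 of 22 DREB, ERF and ZAT genes had a smaller response in dcp5-1 and 0 a larger one (18 and 2 adjusted over the list alone), with a median difference of −1.07 (camera adjusted p 1.24e-14, and adjusted p 0.0901 with an estimated correlation). Of the 13 touch and early wound genes 11 had a smaller response and 1 a larger one, among them CAF1a (−1.95), CAF1b (−1.65) and WRKY40 (−1.63), with a median difference of −0.91 (camera adjusted p 4.53e-09, and adjusted p 0.0901 with an estimated correlation). Of 11 sugar starvation genes 8 were lower in the contrast and 1 higher (10 and 1 adjusted over the list alone), with SEN1 at −0.86 and BXL1 at −0.59 (camera adjusted p 0.000637, and adjusted p 0.0989 with an estimated correlation). Jasmonate genes had a larger response in 15 of 24 and a smaller one in 5 (16 and 5 adjusted over the list alone), with JAZ10 at 1.28 and OPR3 at 0.71 and a median of 0.30 that became −0.31 when the ratios were scaled between arrays (camera adjusted p 4.20e-05, and adjusted p 0.106 with an estimated correlation). Seed storage and maturation genes were higher in 7 of 10 and lower in 1, with CRC at 1.09 and SESA1 at 0.93 (camera adjusted p 0.000637, and adjusted p 0.0901 with an estimated correlation). Root tissue markers were higher in 7 of 12 and lower in 1, with EXPA7 at 0.40 and CASP2 at 0.36 (camera adjusted p 0.00600, and adjusted p 0.106 with an estimated correlation). Guard cell markers were higher in 3 of 5 and lower in 1, with a median of 0.13 and no camera call (adjusted p 0.259). Chloroplast-encoded transcripts were higher in 48 of 66 and lower in 1 (50 and 1 adjusted over the list alone), by a median of 0.19 (camera adjusted p 9.97e-12, and adjusted p 0.212 with an estimated correlation). Heat shock genes were lower in 5 of 8 and higher in 0 (6 and 0 adjusted over the list alone), with MBF1C at −0.64 and HSFA2 at −0.62 (camera adjusted p 0.0453, and adjusted p 0.188 with an estimated correlation). That camera call was lost without WT dye-swap 2 (adjusted p 0.0703), dcp5-1 replicate 1 (0.0519) or dcp5-1 dye-swap 2 (0.0855) and with median centring (0.0860), over a range of 0.0156 to 0.0860. With the ratios scaled between arrays the median was −1.62 for the DREB, ERF and ZAT genes and −1.69 for the touch genes. The median of 0.40 for seed genes was 0.87 with processed signals and 0.93 with the LogRatio column. Of 34 splits of the 8 arrays into 4 and 4, 6 called at least as many lists as the 8 called here. Camera called none of the other 17 lists, among them the effector genes, of which 13 were lower and 6 higher in the contrast (14 and 6 adjusted over the list alone).

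**Figure D3:**
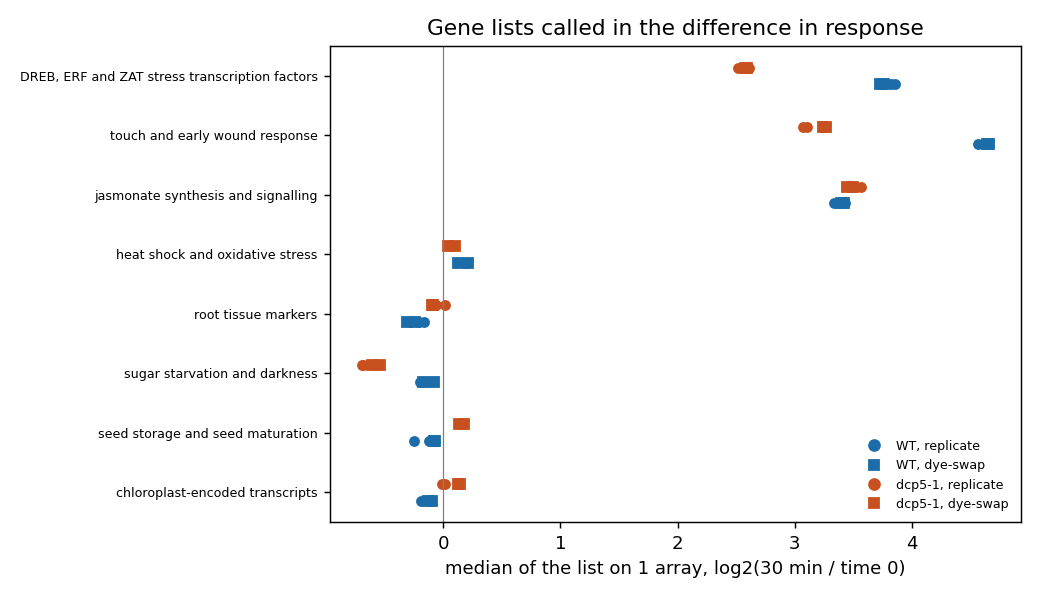
Median log2 ratio of 30 min over time 0 on each of the 8 arrays for the 8 lists that camera called in the difference in response, WT in blue and dcp5-1 in orange, circles for replicates and squares for dye-swaps. Each point is the median of 1 list on 1 array. 0 of the 8 was called with an estimated correlation. The DREB, ERF and ZAT list (median difference −1.07) and the touch list (−0.91) lie lower in dcp5-1 on every array, and the small shift of the jasmonate list (0.30) changes sign when ratios are scaled between arrays.

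The size of the response was compared over genes chosen on other arrays. For the genes with the largest rises in WT, the median log2 rise was 4.26 ± 0.023 (SD, n = 4) in WT and 3.89 ± 0.037 (SD, n = 4) in dcp5-1, a difference of −0.36 (exact two-sided permutation p 0.0286). For the largest rises in dcp5-1 the medians were 3.93 in WT and 3.95 in dcp5-1, a difference of 0.020 that did not pass (exact p 0.429). Choosing genes in 1 genotype favours that genotype, so the rises chosen in WT do not by themselves show a smaller response in dcp5-1. The falls chosen in dcp5-1 share this limit. Falls were deeper in dcp5-1 under both choices: −1.67 against −1.48 for genes chosen in WT (difference −0.18, exact p 0.0286) and −1.76 against −1.39 for genes chosen in dcp5-1 (difference −0.37, exact p 0.0286). With median centring in place of loess, the 3 differences were no smaller (−0.40, −0.22 and −0.42), but none passed, as the arrays of a genotype then overlapped those of the other (exact p 0.171, 0.286 and 0.114). With processed signals the falls chosen in WT differed by −0.032 (exact p 0.257). The difference in rises of genes chosen in dcp5-1 took either sign, at −0.039 with more genes chosen and 0.096 with processed signals (exact p 0.0286 in each).

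The fourth comparison asked how the genotypes differ before dehydration. The genes most raised in dcp5-1 at time 0 included LURP1 (7.75-fold, log2 2.95 ± 0.041 SE, n = 4 per genotype), the transcription factor genes WRKY70 (5.44-fold) and WRKY38 (5.32-fold), PCC1 (4.79-fold), PNP-A (4.75-fold) and THI2.1 (4.90-fold). PCR1, which was not well above background in WT, was at least 7.22-fold higher. BIP3, a chaperone gene of the endoplasmic reticulum (5.26-fold), TAT3 (4.84-fold) and COR15A, a cold-regulated gene (4.74-fold), were higher as well. Lower in dcp5-1 were SAG13 (10.6-fold, log2 −3.41 ± 0.058 SE, n = 4 per genotype), DXPS1 (9.50-fold), AMY1 (6.21-fold), the sugar transporter gene SAG29 (5.64-fold), DIN2 (5.19-fold) and DCP5. CSD2 (9.59-fold) and CSD1 (6.83-fold), the chloroplast and cytosolic copper/zinc superoxide dismutases, CCS, their copper chaperone (5.34-fold), and ARPN, a plantacyanin (4.81-fold), were lower too. For all 20 genes the 4 arrays of one genotype lay above the 4 of the other, as the naming rule required. The limma adjusted p was at most 8.51e-15. In all, 209 genes were at least 2-fold higher and 86 at least 2-fold lower in dcp5-1, in the separate-channel fit and also with the channels of time 0 alone. Without the fold criterion limma called 13693 of 21289 genes, 7037 higher and 6656 lower. In simulated data a mean of 11.1% of such calls were false. Far fewer genes were changed there and the noise was scaled down, so that share cannot be carried over to this count. With the channels of time 0 alone limma called 14202 genes.

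**Figure D4:**
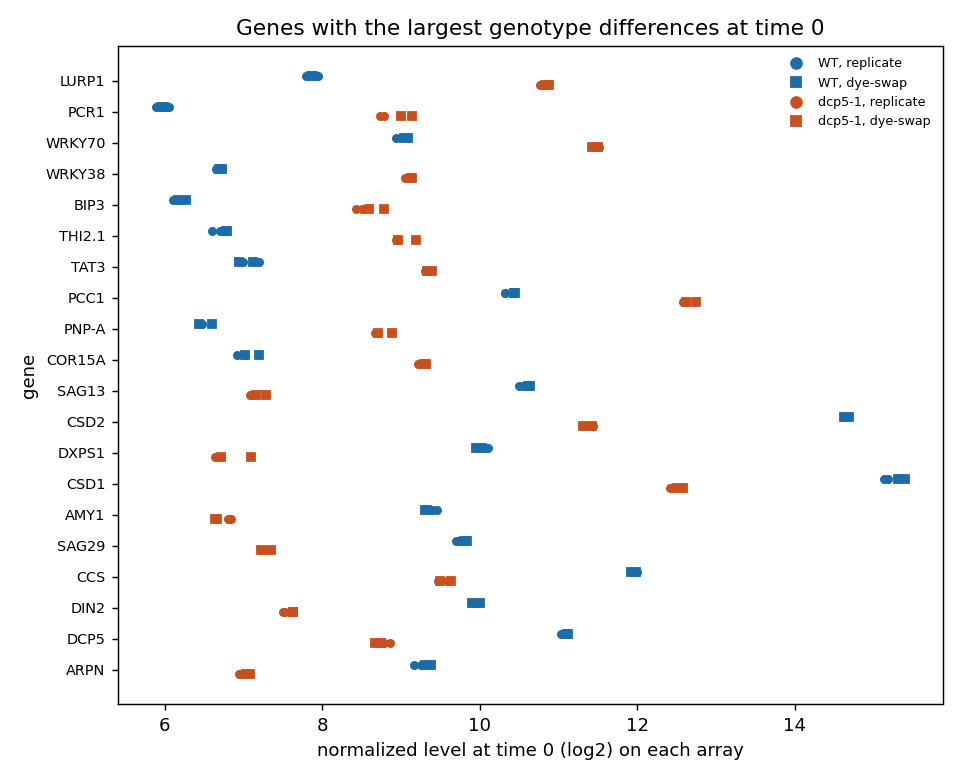
Normalized level (log2) at time 0 on each of the 8 arrays for the 10 genes most raised and the 10 most lowered in dcp5-1 against WT, WT in blue and dcp5-1 in orange, circles for replicates and squares for dye-swaps. Each point is 1 array. The naming rule required the 4 arrays of one genotype to lie apart from the 4 of the other, as for LURP1 (log2 difference 2.95) and SAG13 (−3.41).

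Among the lists at time 0, 16 of 22 DREB, ERF and ZAT genes were higher and 1 lower, with ZAT12 at 1.79, ERF104 at 1.71, CBF2 at 1.63 and ERF5 at 1.42 and a median of 0.61 (camera adjusted p 1.17e-06, and adjusted p 0.177 with an estimated correlation). Of the 13 touch and early wound genes 10 were higher and 1 lower, with ACS6 at 1.92 and a median of 0.90 (camera adjusted p 3.77e-05, and adjusted p 0.177 with an estimated correlation). Heat shock genes were higher in 6 of 8 and lower in 1 (7 and 1 adjusted over the list alone), with HSP90.1 at 1.47 (camera adjusted p 0.00528, and adjusted p 0.227 with an estimated correlation). These lists had a smaller response in dcp5-1 by the camera test above. The sugar starvation list, also lower in that contrast, instead fell more in dcp5-1 (median response −0.62) than in WT (−0.12). At time 0, 3 of its 11 genes were higher and 3 lower, with a median of 0.011 that was −0.0096 with quantile normalization (camera adjusted p 0.945). Salicylate and defence genes were higher in 11 of 16 and lower in 2, with PAD3 at 1.65 and PR2 at 1.64 (camera adjusted p 0.00227, and adjusted p 0.177 with an estimated correlation). Of 66 chloroplast-encoded transcripts 48 were lower and 0 higher (49 and 0 adjusted over the list alone; median −0.23, camera adjusted p 4.93e-08, and adjusted p 0.177 with an estimated correlation). Of 58 mitochondrion-encoded transcripts 45 were lower and 1 higher (46 and 1 adjusted over the list alone; median −0.23, camera adjusted p 1.58e-07, and adjusted p 0.227 with an estimated correlation). Root tissue markers were lower in 8 of 12 and higher in 1, with CASP1 at −0.78 and COBL9 at −0.67 (camera adjusted p 0.00227, and adjusted p 0.227 with an estimated correlation). Guard cell markers had the lowest median of all lists (−0.61) without a camera call (adjusted p 0.151, and fry adjusted p 1.28e-06 in limma). MYB60 (−0.73), SLAC1 (−0.62) and HT1 (−0.61) were the 3 of 5 that were lower, and KAT1 (0.15) was higher. Auxin genes were lower in 11 of 22 and higher in 3 (11 and 4 adjusted over the list alone), with GH3.3 at −1.30 and IAA19 at −1.18 and a median of −0.10 that was 0.030 without normalization between arrays (camera adjusted p 0.0344, and adjusted p 0.227 with an estimated correlation). Seed genes were lower in 6 of 10 and higher in 1, M17 at 1.73 (camera adjusted p 0.0393, and adjusted p 0.227 with an estimated correlation). The camera call was lost without WT replicate 1 (adjusted p 0.0543, with 0.0224 to 0.0543 over the alternatives). The chloroplast, root and seed lists, lower here in dcp5-1, were higher in the contrast of the responses above. Type-A cytokinin regulators were higher in 6 of 9 and lower in 0 (camera adjusted p 0.0448, and adjusted p 0.388 with an estimated correlation). That camera call was lost without WT dye-swap 2 (adjusted p 0.0694) and with processed signals (0.196), no background correction (0.0539) and median centring (0.0541), over a range of 0.0228 to 0.196. With processed signals the medians were larger for heat shock (1.08 in place of 0.50), salicylate (1.17 in place of 0.46), seed (−1.12 in place of −0.40) and mitochondrion-encoded genes (−0.45). Without normalization between arrays the median of all genes was 0.16 in place of 0.0072. The medians were then −0.045 for chloroplast-encoded transcripts, −0.11 for mitochondrion-encoded transcripts and 0.39 in place of 0.19 for type-A regulators.

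The decapping and decay list itself had no camera call in any of the 4 comparisons in which lists were tested. At time 0 10 of its 24 genes were higher in dcp5-1 and 6 lower, DCP5 and its paralogue DCP5-L (−0.34) among the latter, and its median of 0.021, which was −0.0091 with processed signals, and its mean of −0.073 differed in sign. DCP2, the decapping enzyme gene, fell during dehydration by log2 −0.27 in WT and −0.55 in dcp5-1 (difference −0.28, limma adjusted p 6.66e-05, and 0.108 with no dye term, the highest of a range from 2.87e-05). Of the genes used as reporters of mRNA decay, CCL fell 2.05-fold in WT and 2.64-fold in dcp5-1, a difference of log2 −0.37 (limma adjusted p 2.01e-05). SEN1 fell 1.64-fold in WT and 2.98-fold in dcp5-1, a difference of −0.86 (limma adjusted p 3.66e-10), and EXLA1 rose 4.80-fold and 6.87-fold, a difference of 0.52 (limma adjusted p 5.47e-08). At time 0 CCL differed by −0.064, which did not pass (limma adjusted p 0.295, with 0.0353 to 0.983 over the alternatives), while SEN1 (−0.33, 7.44e-05 by limma) and EXLA1 (−0.43, 6.63e-09 by limma) were lower in dcp5-1.

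At 30 min 148 genes were at least 2-fold higher and 74 at least 2-fold lower in dcp5-1, and limma called 13973 of 21289 genes without the fold criterion, 6590 higher and 7383 lower. The DREB, ERF and ZAT genes were by then lower in dcp5-1 in 16 of 22 and higher in 2, with a median of −0.39. The touch genes were lower in 5 of 13 and higher in 2, with a median of −0.075 that was 0.16 without normalization between arrays. Salicylate and defence genes were higher in 12 of 16 and lower in 1 (median 0.38), and mitochondrion-encoded transcripts were lower in 39 of 58 and higher in 2 (median −0.19, and −0.33 with processed signals). Jasmonate genes were higher in 11 of 24 and lower in 3 (median 0.17). Guard cell markers were lower in 4 of 5 and higher in 1 (median −0.46), and root tissue markers lower in 7 of 12 and higher in 2 (median −0.16). Without normalization between arrays, which put the median of all genes at 0.14 in place of −0.015, the medians were −0.16 for the DREB, ERF and ZAT genes, 0.40 for jasmonate genes, −0.058 for root tissue markers and −0.073 for mitochondrion-encoded transcripts.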

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

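Of the tests in this part, the comparison of the DREB, ERF, ZAT and touch genes at 30 min, together and by list, was chosen after the result was seen. Chance alone gives about 1 lone value in 20 groups of arrays. Of 220 groups of 4 arrays examined, 6 held an array far from the other 3. These were the share of probes well above background in Cy3 on dcp5-1 dye-swap 1 (74.6%), the median of the largest WT falls on WT replicate 1 (−1.45), P1R1's response on dcp5-1 dye-swap 1 (−2.92), CYP94C1's response on WT replicate 2 (4.2), and at time 0 the levels of WRKY38 on dcp5-1 replicate 2 (9.05) and THI2.1 on dcp5-1 dye-swap 1 (9.19).

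A difference between the genotypes in the response to dehydration was tested by the contrast in limma, which called 9526 genes, 189 of them at least 2-fold. Single genes that differed were SAG13 (2.77), DXPS1 (2.25), LTP4 (2.09), NATA1 (2.04), CYP94C1 (1.84), AMY1 (1.82), KTI1 (1.77), ELI3-2 (1.77), DIN2 (1.76) and GPT2 (1.58), and, with a smaller or more negative response in dcp5-1, THI2.1 (−2.70), NUDT21 (−2.60), CBF2 (−2.59), ERF5 (−2.45), RHL41 (−2.32), DIC2 (−2.30), STZ (−2.30), ERF104 (−2.23), ACS6 (−2.19) and NUDT4 (−2.08). Among the genes always named, EXLA1 (0.52), SEN1 (−0.86), CCL (−0.37) and DCP5 (−0.15) differed. The response size differed for the largest rises in WT (−0.36) and the largest falls in WT (−0.18) and in dcp5-1 (−0.37). Choosing genes in 1 genotype favours that genotype, which bears on the first and the last of these. Lists called by camera at its preset correlation, of which 0 was called with an estimated one (camera adjusted p 0.0901 to 0.212), had medians as follows: the DREB, ERF and ZAT genes (−1.07), the touch genes (−0.91), jasmonate (0.30, and −0.31 with ratios scaled between arrays), heat shock (−0.16), root markers (0.19), sugar starvation (−0.34), seed genes (0.40) and chloroplast-encoded transcripts (0.19).

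The counts were repeated for other splits of the 8 arrays into 4 and 4, except the split along the dye, which could not be fitted. Among 34 splits, only the real one (1 of 34) reached 9526 genes for the difference in response, and the highest of the others called 0. Every other split mixed the genotypes, and with them the slides, within a group, which adds their difference to the spread and lowers the count. The splits therefore cannot exclude a chance difference between the slides as the source of the 9526 calls. With the intraspot correlation estimated anew, the real split called 13683 genes at time 0 and 13960 at 30 min, and for each only the real split (1 of 34) reached its count, with 0 as the highest of the others. For gene lists at time 0 the real split called 10, also reached by 1 of 34, and the highest other called 8. For gene lists in the difference 6 of the 34 splits called at least the real 8, and the highest called 10, so chance is not excluded for the number of lists. For the response within a genotype only 8 arrangements of signs exist, too few for a share under 0.05. The real WT count of 15317 was reached by 1 of 8, with 0 as the highest other, and the real dcp5-1 count of 16456 by 1 of 8, with 8 as the highest other.

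The first pattern weighed is the smaller rise of the 35 DREB, ERF, ZAT and touch genes in dcp5-1, with a median difference in response of −0.96 and a median of 0.71 at time 0. Compression of all large ratios on the dcp5-1 arrays is argued against, since 629 other genes that rose at least 4-fold in WT had a median difference of −0.076. Those genes were not matched to the 35 in size of rise, and 24.6% of them had a difference below −0.5 (interquartile range of the 629 genes 0.77). A smaller rise in dcp5-1 was thus not confined to the 35 genes. The 200 largest rises, from which the 35 genes were not taken out, differed by −0.36 when chosen in WT and by 0.020 when chosen in dcp5-1. Background correction and normalization within arrays are argued against too, as the median difference of the 35 genes was −1.0 or lower under 3 alternatives. A candidate explanation is that dcp5-1 seedlings held these transcripts higher before dehydration and reached the same level at 30 min. For the DREB, ERF and ZAT genes this is argued against as the whole cause under the main normalization, as their median at 30 min was −0.39 ± 0.12 (SE over the 22 genes) and all 4 dcp5-1 arrays lay below all 4 WT arrays (exact two-sided permutation p 0.0286, the smallest possible). The SE over arrays was 0.041. Genes of a list are not independent, so the SE over genes may be too small. With that SE the median cleared only narrowly a bound that was set after the result was seen. Without normalization between arrays, which put the median of all genes at 0.14, their median was −0.16, short of the bound set for arguing against this explanation. For the touch genes it remains open, as their median was −0.075 ± 0.090 (SE over the 13 genes) with 5 lower and 2 higher, and over all 35 genes the median of −0.23, with 21 lower and 4 higher, lay between the bounds set, while for both lists the slide cannot be told apart from the genotype, as 0 slides held both.

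Probes whose names hold no locus were outside the comparisons of genes. Of the 2497 that were well above background, limma called 128 at least 2-fold in WT (115 higher, 13 lower), 124 in dcp5-1 (101 higher, 23 lower) and 6 in the difference (2 higher, 4 lower). No biological explanation was tested for them.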

How the results depend on the processing

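None of the alternatives in this part was chosen after the results were seen. Over the alternatives, 6197 of the values for named genes and lists kept their side of the threshold with no called value changing sign, 170 lost their call, 9 gained one and 7 reversed. The 7 that reversed were the fry direction of expansins in WT (fry adjusted p 8.36e-05 in limma, a test of another question), RPSAb in dcp5-1 with median centring (−0.029) and with the LogRatio column (−0.0064), and in WT with that column RPSAb (−0.048), LSM1B (−0.0080), RPL18AA (−0.073) and DCP5 (−0.086), the last 2 of which passed the limma threshold in the reversed direction (adjusted p 0.0195 and 0.0499). In WT that column put the median of all genes at −0.14, further below 0 than any of these WT values. Whether this shift alone turned their signs was not tested. A fold of at least 2 left 1788, 2017, 189, 295 and 222 genes for WT, dcp5-1, the difference, time 0 and 30 min, by construction. Without a dye term limma called 5412 genes for the difference (2323 higher, 3089 lower), since the dye effect then counts as spread. The estimated correlation left 5, 0, 0 and 0 lists called for WT, dcp5-1, the difference and time 0, and fry called 22, 22, 18 and 21. The response size lost its calls with median centring (−0.40, −0.22 and −0.42 for rises in WT, falls in WT and falls in dcp5-1) and with processed signals for falls in WT (−0.032). Rises chosen in dcp5-1 gained one with processed signals (0.096), with more genes chosen (−0.039, a reversed sign) and as a slope (0.020), and the cause was not tested. With 1 array left out, rises in WT lay between −0.38 and −0.35, falls in WT between −0.19 and −0.17 and falls in dcp5-1 between −0.38 and −0.36, with a smallest possible exact p of 0.0667 where the array was of the genotype used for choosing. The direction of called genes moved with the scaling: higher and lower were 5289 and 12134 in WT and 5877 and 11365 in dcp5-1 with the LogRatio column, which shifted the median of all genes by −0.14 and −0.12, 5291 and 12135, and 5876 and 11362 with the deposited series table, 6056 and 8904, and 6385 and 9883 with median centring, and 10435 and 2318 at time 0 and 9673 and 2608 at 30 min with no normalization between arrays. Leaving out 1 array gave 8141 to 9257 genes for the difference and 12612 to 13951 at time 0. The replicate label as a block shared by the genotypes gave 15560, 16643, 9929, 14088 and 14328 genes for WT, dcp5-1, the difference, time 0 and 30 min, and ended the camera call of heat shock genes in the difference (adjusted p 0.0631, with 0.0156 to 0.0860 over the alternatives). After the dye effect, arrays with one label in both genotypes correlated at −0.13 to 0.058, and 0 of 8 correlated best with their own label, so no block was used. The slide as a block was not run, since each slide held 1 genotype. Signal over background limits the calls to the 21331 genes tested.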

Other observations

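The tests in this part followed from the lower copper protein genes at time 0, and were set down before their own values were seen. Genes tied to copper use were looked at in dcp5-1 before dehydration, against a median absolute difference of 0.17 over all genes. The laccases, copper enzymes of the cell wall, were chosen as targets of copper microRNAs and do not stand for laccases in general. Of the 7 tested, LAC4 (−1.66), LAC2 (−1.51), LAC3 (−1.11), LAC17 (−1.07), LAC7 (−0.45) and LAC13 (−0.21) were lower at time 0 and LAC12 (0.23) was higher. FSD1, the iron superoxide dismutase that stands in for the copper enzymes, was higher by log2 0.92, as were the copper transporter genes COPT2 (0.51), COPT1 (0.26) and COPT6 (0.12), the reductase genes FRO5 (0.36) and FRO4 (0.17), and ZIP2 (0.14). At 30 min the differences were −2.36 for CSD1, −2.95 for CSD2, −2.91 for CCS and −1.26 for ARPN. For the other genes they were then 0.85 for FSD1, 0.046 for COPT2, 0.047 for COPT1, −0.33 for COPT6, 0.30 for FRO5, −0.14 for FRO4 and 0.20 for ZIP2, and −1.21 for LAC4, −1.50 for LAC2, −0.97 for LAC3, −0.78 for LAC17, −0.080 for LAC7, −0.15 for LAC13 and −0.044 for LAC12.

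The second pattern weighed is the lower CSD1, CSD2, CCS and ARPN in dcp5-1 at time 0. The median of the 4 genes was −2.39 or lower under 4 alternatives of background correction and normalization, so their lower level did not depend on these settings. The genes were picked from the largest differences of this same comparison, so the test was unlikely to turn out otherwise. A candidate explanation is a state like that of copper shortage in dcp5-1 seedlings, in which these genes and the laccases fall while genes of copper uptake rise. The 7 laccases had a median of −1.07, which this explanation needs, but the 7 genes raised under shortage had a median of 0.257, which lies within the standard error of its middle gene, COPT1 (0.047), of the bound set for it, so the test leaves this explanation open. The slide cannot be told apart from the genotype, as 0 slides held both, and copper itself was not measured.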
